A study of Mus musculus with 8 samples.

How the data were processed

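Liver RNA of wildtype mice and of mice with a hepatic Foxo1 knockout was sequenced, with 4 libraries per group. Total RNA was extracted with Trizol, treated with DNase and column-purified, and libraries followed the usual Illumina preparation, per the labels' protocols. TopHat2 2.1.0, HTSeq and Cufflinks 2.2.1 and the mouse genome build mm10 are named in the submitters' processing notes without a role or an order. The gene annotation, read length and strand setting are not given in the sources used here.

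The deposited table holds FPKM, a fragment count scaled to transcript length and to the mapped fragments of the library, for 25690 Ensembl genes. This unit was read from the values and from the tools named in the submitters' processing notes, since the header gives only library names. The values are not whole, and 51.2% of those above 0 have 7 or more significant digits, of which 95.3% end in 5, as means of a pair of estimates with fewer digits would. Why the authors' values have this form is not given in the sources used here. FPKM are not counts, so no count model was used. Some genes are listed at 0 where the other libraries are high: Alb is at 0 in knockout 10 and between 20877 and 27822 FPKM elsewhere, and Mup1 is at 0 throughout. An exact 0 can be a failed estimate and is not described as absence, but the main fit took it as a value of 0. Of the tested genes 37 have a 0 in at least 1 library, and 1 of these was called.

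Depth was estimated from genes with 1 annotated transcript longer than 1500 bases, whose lowest values cluster at the FPKM of a single fragment. It came to 27.0 M to 35.2 M fragments per library, which is an estimate, since counts were not used here. Gene names were found for 24807 genes. Names, coordinates, transcript lengths and GC content came from GENCODE mouse release M21 on the same build, with the longest transcript taken as the length, which 10149 of the tested genes had.

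Groups were taken from the genotype and title labels. Genes with a mean of at least 1 FPKM over the 8 libraries were kept, 10250 in number, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 with genotype as the single term, moderated variances with a mean trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of low genes. Without strand information, reads of overlapping or antisense genes cannot be told apart, and Cyp2a, Cyp2c, Cyp3a, Gsta, Ces1, Mup and Serpina1 genes share reads with similar copies. The test design, the 34 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, leaving out Foxo1. Camera compares a list with the other genes, whose median log2 change was -0.08, and for 10 lists, of which 0 were called, the signs of the median, the mean and the test differ.

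The genes named are the FoxO family, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, Igfbp1, G6pc, Pck1 and Irs2 in every case, up to 4 members with the smallest adjusted p from each called list and from the FoxO1 targets, up to 3 passing members from each list not called, and genes that met the outlier criterion. One gene that this rule would name is not reported here. Alb, Mup1, Mup17, Gm27747, Cyp2a5, Cyp2e1, Gstt1, Fmo1, Nr1i3, Cth, Tdo2, Haao and Hgd were named after their values were seen.

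The steps were tested on simulated data drawn from the means and spreads of the 10250 genes in the comparison of knockout with wildtype. Of 100 genes changed by 2 on the log2 scale 96% were called in the right direction, and of 100 changed by 1, 89%. Unchanged genes made up 4.15% of the 193 calls. With no change 0 of 10250 genes and 0 lists were called. These draws treat genes as independent, which real genes are not.

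Alternatives were other pseudocounts, filters, scalings, variance models, library weights, the number in the titles as a block, leaving out each library, other list tests and other thresholds. Removal of the trends along length and GC content, leaving out knockouts 3 and 11 together, leaving out genes with a 0, and scaled library checks were chosen after seeing the data. The length trend was first removed with a least-squares loess and then with a symmetric one of span 0.5. Both are given for gene counts and list medians, and values of named genes are those of the symmetric one.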

Results

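Liver RNA of mice with a hepatic knockout of Foxo1, the gene of a forkhead transcription factor that insulin signalling keeps out of the nucleus, was compared with liver RNA of wildtype controls. There were 4 wildtype libraries, with the numbers 1, 3, 10 and 12 in their titles, and 4 knockout libraries, with the numbers 3, 9, 10 and 11. The deposited table gave FPKM for 25690 genes. The FPKM value of a single fragment implied a depth of 27.0 M fragments (wildtype 3) to 35.2 M fragments (knockout 11) per library. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these libraries.

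Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336 to 52353221, mm10, plus strand, protein-coding) was the targeted gene and was low in each knockout library. Its FPKM was 3.35 ± 0.341 (SD, n = 4) in wildtype and 0.269 ± 0.0743 (SD, n = 4) in knockout liver, a 12.5-fold lower mean. The knockout libraries lay between 0.212 and 0.375, and the wildtype libraries between 3.01 and 3.81. On the log2(FPKM + 1) scale Foxo1 fell by 1.78 (SE 0.09, limma adjusted p = 3.62e-05). Foxo3 was at 5.70 ± 0.973 in wildtype and 4.12 ± 0.368 in knockout liver and did not pass (limma adjusted p = 0.0578), although it did with the trend along transcript length described below removed (limma adjusted p = 0.0487). Foxo4 was at 6.69 ± 0.459 and 5.50 ± 0.396 and did not pass either (limma adjusted p = 0.0980). Foxo6 was listed above 0 in wildtype 1, at 0.0127, and in knockout 10, at 0.0115, and at 0 in the other libraries.

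**Figure D1:**
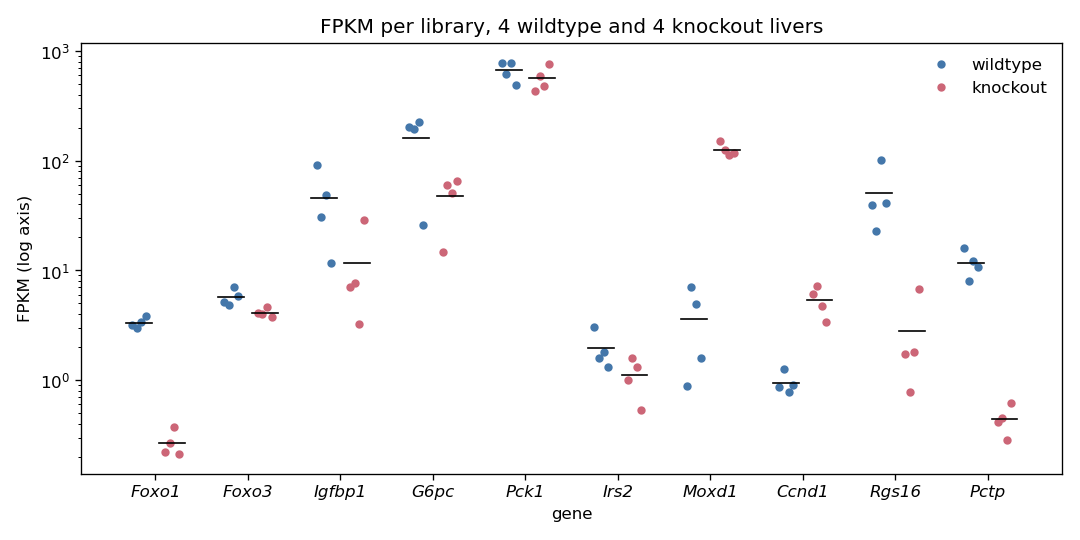
FPKM on a log axis for 10 genes, with 1 point per library (4 wildtype, 4 knockout) and a black line at the mean of each group. Foxo1 lies between 0.212 and 0.375 in the knockout libraries and between 3.01 and 3.81 in the wildtype libraries, while G6pc and Igfbp1 have a low wildtype point, wildtype 12, at 26.2 and 11.6.

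Genes raised in the knockout liver were led by Moxd1, a monooxygenase-like gene, which went from 3.63 ± 2.90 to 126 ± 17.7 FPKM (SD, n = 4), and by the chemokine gene Cxcl14, which went from 0.50 ± 0.457 to 18.2 ± 15.5. Their log2 changes were 5.01 (SE 0.41, limma adjusted p = 0.000706) and 3.31 (SE 0.55, limma adjusted p = 0.00648). Tsku, which encodes a secreted leucine-rich protein, rose by 2.23 on the log2 scale, Slc22a7, an organic anion transporter gene, by 1.76, and Rarres1 by 1.75. Dnaic1, Lrg1, Crybb3 and Slc3a1 completed the rises by size, with log2 changes of 2.55, 2.19, 2.08 and 1.80. Trat1 was listed at 0 in the 4 wildtype libraries and at 10.5, 1.60, 1.39 and 4.70 FPKM in knockouts 3, 9, 10 and 11. Within the knockout group Lrg1 was at 1171 and 872 FPKM in knockouts 3 and 11 and at 271 and 261 in knockouts 9 and 10, against 114 ± 14.5 in wildtype. Crybb3 did not pass without wildtype 1, 3, 10 or 12 or knockout 11, each alone (limma adjusted p up to 0.0690), and Slc3a1 did not without wildtype 1, 3, 10 or 12 or knockout 3 or 11 (up to 0.104). Without both knockouts 3 and 11 the log2 changes of Trat1, Lrg1, Crybb3 and Slc3a1 were 1.32, 1.22, 1.05 and 0.87, in place of 2.17, 2.19, 2.08 and 1.80, and Slc3a1 did not pass (0.0894). With no filter on low values Crybb3 (0.0677) and Slc3a1 (0.0952) did not pass. Nor did Slc3a1 with the length trend described below removed (0.0518), median-ratio scaling (0.0505), quantile normalization (0.0531) or a robust variance model (0.0727).

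Genes lowered in the knockout liver were led by Rgs16, a regulator of G protein signalling, which went from 51.3 ± 34.3 to 2.78 ± 2.72 FPKM (SD, n = 4), and by Pctp, a phosphatidylcholine transfer protein gene, which went from 11.7 ± 3.35 to 0.442 ± 0.137. Their log2 changes were -3.82 (SE 0.50, limma adjusted p = 0.00370) and -3.11 (SE 0.18, limma adjusted p = 5.43e-05). The cytochrome P450 genes Cyp2c37, Cyp2c54, Cyp2c38 and Cyp2c50 fell by 2.94, 2.67, 2.35 and 2.07 on the log2 scale. They are neighbouring, similar genes of chromosome 19 that can share reads, so the split between them is uncertain. Angptl8, a secreted regulator of triglyceride clearance, fell by 2.31, Gm10804 by 2.16, Cnmd by 2.14 and Jun, an immediate early transcription factor gene, by 2.06. Angptl8 did not pass without knockouts 3 and 11 (limma adjusted p = 0.107).

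In all, 277 genes were higher and 1195 lower in the knockout liver among 10250 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 38 and 63 of them changed by at least 1 on the log2 scale. The groups did not overlap for 1397 of the 1472 genes, which passing the threshold largely entails. Among all tested genes the share was 21.3%, where chance gives 2.86% per gene, but genes vary together, so this comparison is not a test. The share of higher genes, 18.8%, depended on the scaling. It was 40.2% with median-ratio scaling (485 higher, 720 lower), 41.9% with quantile normalization (470 and 652), 40.3% with the trend along GC content removed (549 and 812), and 46.9% or 39.6% with the trend along transcript length removed by a symmetric or a least-squares loess (516 and 585, or 458 and 698). Without knockouts 3 and 11, which had high acute phase transcripts, 199 genes were higher and 656 lower. Single libraries also moved the counts: without wildtype 1 they were 102 and 599, without wildtype 3 160 and 896, without wildtype 10 145 and 744, without wildtype 12 193 and 745, and without knockout 3 161 and 725.

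The share of genes called lower decreased with transcript length. Of the 1015 shortest genes, with transcripts of 85 to 1155 bases, 36.1% were lower and 0.788% higher, and their median log2 change was -0.31. Of the 1015 longest genes, 2.86% were lower and 3.05% higher, and the median was 0.01. Across genes, which are not independent replicates, Spearman's rho of the log2 change with length was 0.261.

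**Figure D2:**
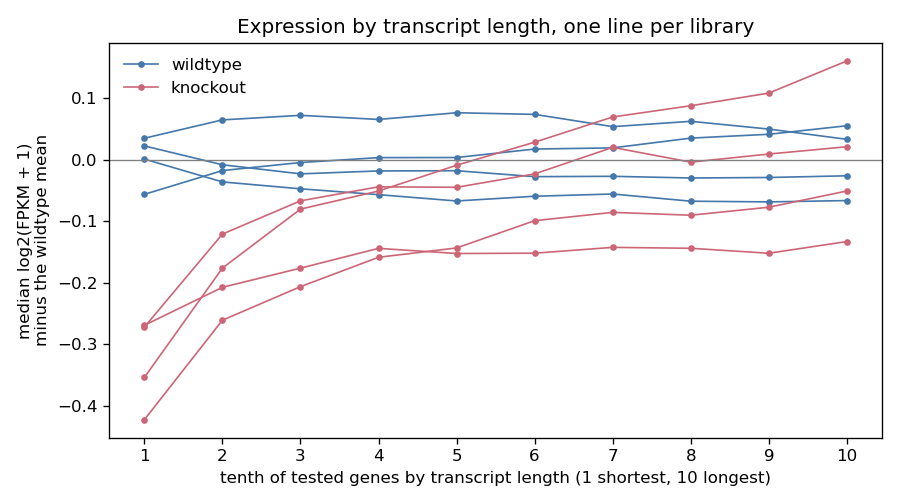
Median of log2(FPKM + 1) minus the wildtype mean in 10 groups of tested genes ordered by transcript length, with 1 line per library (blue, wildtype; red, knockout). In the shortest genes the knockout libraries lie between -0.42 and -0.27 and the wildtype libraries between -0.06 and 0.04.

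Known FoxO1 targets in liver were examined as a list fixed before the data were examined. Of 28 tested members 4 fell, and 4 did so when adjusted over the list alone. These were Apoc3, an inhibitor of triglyceride clearance (log2 change -0.73, SE 0.14, limma adjusted p = 0.0115), the mitochondrial superoxide dismutase gene Sod2 (-0.46, 0.0150), the insulin receptor gene Insr (-0.32, 0.0274) and Fst (-0.88, 0.0402). With the length trend removed by symmetric loess, Apoc3 (-0.36, limma adjusted p = 0.0746) and Fst (-0.80, 0.0844) did not pass, while Apoc3 passed with the least-squares loess. With quantile normalization Sod2 (-0.29, 0.0600), Insr (-0.26, 0.0501) and Fst (-0.84, 0.0655) did not, with median-ratio scaling Insr (0.0683) and Fst (0.0704) did not, and with no filter on low values Fst did not (0.0973). Sod2 did not pass without wildtype 1 (0.0551), Insr without wildtype 1, 10 or 12 or knockout 3 or 11, each alone (up to 0.0854), and Fst without any single library but wildtype 12 (up to 0.106). Without both knockouts 3 and 11, Insr and Fst did not pass (0.106 and 0.14), and with the GC trend removed they did not either (0.0737 and 0.0884). The list as a whole was not called by camera (adjusted p = 0.313, and 0.878 with an estimated correlation). Igfbp1, which encodes an insulin-like growth factor binding protein, was at 45.7 ± 34.0 and 11.7 ± 11.5 FPKM (log2 change -1.92, SE 0.67, limma adjusted p = 0.0883). G6pc, the catalytic subunit of glucose-6-phosphatase, was at 163 ± 92.2 and 47.8 ± 22.8 FPKM (-1.55, SE 0.70, limma adjusted p = 0.171). Neither passed. Without wildtype 12, where G6pc was 26.2 against 194 to 228 FPKM in the other wildtype libraries, G6pc passed (-2.29, limma adjusted p = 0.0234) and so did Igfbp1 (-2.44, limma adjusted p = 0.0449), and Igfbp1 also passed without knockout 11 (-2.46, limma adjusted p = 0.0337) and with library weights (-2.42, limma adjusted p = 0.0415). Over all alternatives the adjusted p lay between 0.0234 and 0.419 for G6pc and between 0.0337 and 0.268 for Igfbp1. Pck1 (-0.25, limma adjusted p = 0.465) and Irs2 (-0.47, limma adjusted p = 0.161) did not pass.

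Camera called 8 of 32 tested gene lists with a preset inter-gene correlation of 0.01, 4 in each direction, and 0 with an estimated correlation. Among the lists, 22 of 29 respiratory chain genes fell and 0 rose (27 and 0 adjusted over the list alone, camera adjusted p = 1.78e-12, and adjusted p = 0.690 with an estimated correlation). Examples were Ndufa1 and Ndufa2 of complex I, which fell by 0.95 and 0.94, Cox7a2 of complex IV, which fell by 0.78, and Uqcrfs1 of complex III, which fell by 0.65. Many members are short genes, and with the length trend removed 16 fell, the list median went from -0.52 to -0.33, and the log2 changes of Ndufa1, Ndufa2, Cox7a2 and Uqcrfs1 were -0.49, -0.53, -0.40 and -0.43. Of 39 genes of cytochrome P450 and drug metabolism 17 fell and 2 rose (23 and 4 adjusted over the list alone, camera adjusted p = 0.00130, and adjusted p = 0.690 with an estimated correlation). With the length trend removed 12 of them fell, and the list median went from -0.55 to -0.37 (camera adjusted p = 0.000162). Without knockouts 3 and 11 the number was 15 (camera adjusted p = 0.000131). Both of these tests used the preset correlation.

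Of 32 acute phase genes, those of blood proteins that the liver makes in inflammation, 2 rose and 0 fell (0 adjusted over the list alone, camera adjusted p = 2.48e-09, and adjusted p = 0.690 with an estimated correlation). These were the complement gene C3 (log2 change 0.82, limma adjusted p = 0.0234) and the fibrinogen gene Fga (0.97, limma adjusted p = 0.0492), and neither passed without wildtype 1, 3, 10 or 12 or knockout 11, each alone (limma adjusted p up to 0.0645 for C3 and 0.12 for Fga). With no filter on low values C3 (0.0624) and Fga (0.116) did not pass. Fga did not pass with the length trend removed (0.0598), the GC trend removed (0.0535), median-ratio scaling (0.0589) or a robust variance model (0.0507) either. Saa1 was at 28413 and 33012 FPKM in knockouts 3 and 11, at 573 and 266 in knockouts 9 and 10 and at 117 ± 52.8 in wildtype, and did not pass (limma adjusted p = 0.0528), although it did without knockout 9 (0.0357) or knockout 10 (0.0172), with a mean FPKM of at least 5 (0.0406), with library weights (0.0277) and with genes with a 0 left out (0.0488). The list median per library was 2.0 and 1.43 above the wildtype mean in knockouts 3 and 11, and 0.13 and 0.14 in knockouts 9 and 10, and without knockouts 3 and 11 the list was not called (camera adjusted p = 0.0557). In that comparison 3 of its genes were higher, C3 (0.50, limma adjusted p = 0.0377), Fga (0.48, 0.0485) and Saa1 (1.81, 0.0417), and 2 were lower. The neutrophil genes S100a8 and S100a9 were at 31.4 and 24.3 FPKM in knockout 3 and at 77.2 and 57.5 in knockout 11, and at most at 2.63 in knockouts 9 and 10. Of the 3 tested lymphocyte and neutrophil markers 0 passed in limma and 2 had an unadjusted p under 0.05. Adjusted over the list alone 2 passed, Cd4 and S100a9 (camera adjusted p = 0.0343, and adjusted p = 0.690 with an estimated correlation). S100a9 passed in limma with library weights (limma adjusted p = 0.0448) and without knockout 9 (0.0353). The list was not called without wildtype 10 (0.0569), knockout 3 (0.0852) or knockout 11 (0.0735), nor with the length trend removed (0.0882), and its median in wildtype 12, 0.34, was above that in knockout 9, 0.13.

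**Figure D3:**
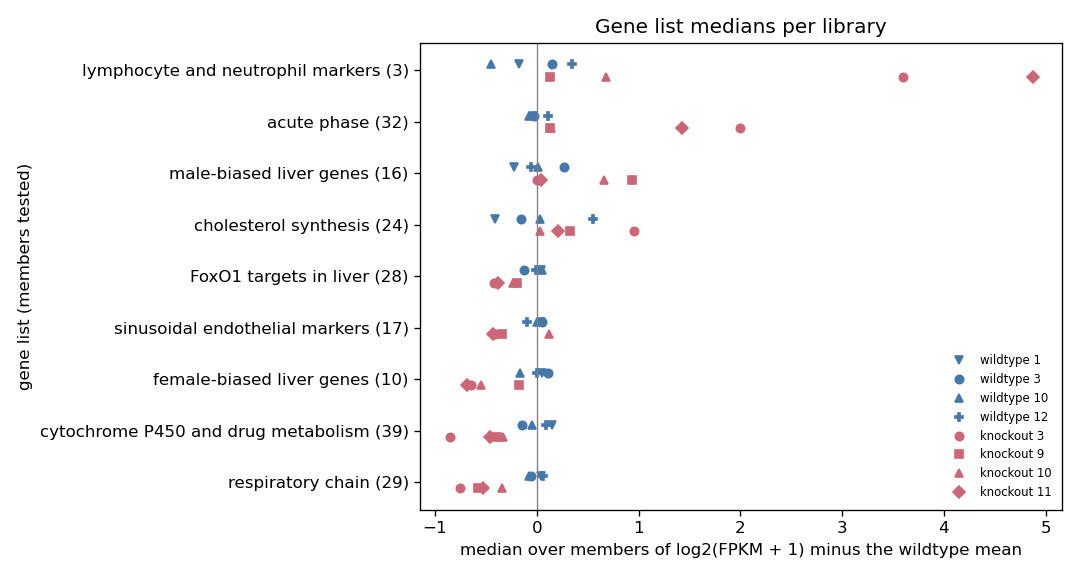
Median over the members of 9 gene lists of log2(FPKM + 1) minus the wildtype mean, with 1 symbol per library (blue, wildtype; red, knockout) and the number of tested members in parentheses. The acute phase median is 2.0 and 1.43 in knockouts 3 and 11 and 0.13 and 0.14 in knockouts 9 and 10, whereas the respiratory chain median lies between -0.75 and -0.35 in the 4 knockout libraries.

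Of 16 tested genes known for higher expression in male liver 5 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 9.13e-05, and adjusted p = 0.690 with an estimated correlation), among them Moxd1, Cyp7b1, an oxysterol hydroxylase gene (0.99), Serpina1e, which has near-identical copies (1.27), and Susd4 (0.62). The list median was 0.94 and 0.66 above the wildtype mean in knockouts 9 and 10 and 0.0063 and 0.044 in knockouts 3 and 11, below the 0.27 of wildtype 3, and without knockouts 3 and 11 the number of higher genes was 7 (camera adjusted p = 2.92e-08). Cyp7b1 did not pass without wildtype 1 or 12 (limma adjusted p up to 0.0609), Serpina1e without wildtype 1 or 12 or knockout 3 (up to 0.0575) and Susd4 without wildtype 3 or 10 or knockout 3, 9 or 10 (up to 0.0963). Serpina1e and Susd4 did not pass without both knockouts 3 and 11 (0.105 and 0.102) or with no filter on low values (0.0763 and 0.0851) either, nor Susd4 with library weights (0.0822). Of 10 tested genes known for higher expression in female liver 4 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0213, and adjusted p = 0.690 with an estimated correlation). These were Cyp3a16 (-0.70), Fmo2 (-0.75), Acot3 (-1.60) and Cyp2a4 (-1.29), which is similar to Cyp2a5. The list median in knockout 9, -0.17, was at the level of wildtype 10, -0.17, and without knockouts 3 and 11 Fmo2 and Acot3 did not pass (limma adjusted p = 0.0629 and 0.0614). Cyp2a4 did not pass without wildtype 1, 10 or 12 or knockout 3 (limma adjusted p up to 0.0605) or with no filter on low values (0.0560), and the list was not called without knockout 10 (camera adjusted p = 0.0554).

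Of 24 cholesterol synthesis genes 1 rose, Dhcr7 (1.19, limma adjusted p = 0.0422), and 0 passed when adjusted over the list alone (camera adjusted p = 9.13e-05, and adjusted p = 0.828 with an estimated correlation). The list median was 0.55 above the wildtype mean in wildtype 12, higher than the 0.32, 0.030 and 0.21 of knockouts 9, 10 and 11, and 0.95 in knockout 3. Without wildtype 12 the camera adjusted p was 3.91e-07. Dhcr7 did not pass without wildtype 1, 3 or 10 or knockout 3 or 11 (limma adjusted p up to 0.113), nor with the length trend removed (0.0509), no filter on low values (0.101) or a robust variance model (0.0607). Without both knockouts 3 and 11 it did not pass (0.68, limma adjusted p = 0.177), and the list was not called (camera adjusted p = 0.107). Of 17 sinusoidal endothelial markers 4 fell and 0 rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.0392, and adjusted p = 0.945 with an estimated correlation). These were Stab1, a scavenger receptor gene (-1.02), Egfl7 (-0.78), Fcgr2b (-0.59) and Bmp2 (-0.39), and without knockouts 3 and 11 0 of the 17 passed and the list was not called (camera adjusted p = 0.242). Nor was it called without wildtype 1 (0.0872), wildtype 3 (0.135), knockout 3 (0.0871), knockout 9 (0.190) or knockout 11 (0.0924), each alone. Its median was 0.12 above the wildtype mean in knockout 10 and -0.41, -0.34 and -0.43 in knockouts 3, 9 and 11, and without knockout 10 the camera adjusted p was 7.44e-05. Stab1 did not pass without wildtype 1 (limma adjusted p = 0.0507), nor Bmp2 without wildtype 1, 3, 10 or 12 or knockout 3 (up to 0.0723).

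The other lists were not called by camera. The length trend of the knockout libraries and the high acute phase transcripts of knockouts 3 and 11, described above, apply to them too. In bile acid synthesis and transport 8 of 28 genes fell and 1 rose (8 and 1 adjusted over the list alone), and the falls included the bile salt export pump gene Abcb11 (-1.23), Abcc3 (-1.32) and Klb (-0.71). In urea cycle and amino acid breakdown 8 of 42 fell and 2 rose (8 and 2 adjusted over the list alone), with Agxt (-0.64), Otc (-0.63) and Prodh2 (-0.46) among the falls. In oxidative stress defence 8 of 24 fell and 1 rose (10 and 2 adjusted over the list alone), with Gsta2 (-1.99) and Txn1 (-0.62) among the falls. In lipoproteins and sterol transport 6 of 28 fell and 1 rose (7 and 1 adjusted over the list alone), with Apoa2 (-1.12) and Apoc4 (-0.59) among the falls. Of 15 immediate early genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with Jun, Jund (-0.65) and Gadd45b (-0.90) among the falls. In insulin signalling 4 of 28 fell and 1 rose (5 and 1 adjusted over the list alone), with Trib3 (-1.81) and Rheb (-0.49) among the falls. In fatty acid and triglyceride synthesis 3 of 27 rose and 1 fell (3 and 1 adjusted over the list alone), with Fads2 (0.93) among the rises and Mid1ip1 (-0.92) as the fall. Txn1 did not pass without wildtype 1 (limma adjusted p = 0.0572), Gadd45b without wildtype 1 or knockout 3 (up to 0.0572) and Mid1ip1 without wildtype 3, 10 or 12 (up to 0.0569). With the length trend removed, Txn1 (-0.34, limma adjusted p = 0.0848), Gadd45b (-0.67, 0.0808) and Mid1ip1 (-0.79, 0.0525) did not pass, and without both knockouts 3 and 11 Mid1ip1 (0.0551) and Rheb (0.0669) did not. With quantile normalization Agxt was at -0.39 and passed, and Otc (-0.39, 0.0721), Prodh2 (-0.24, 0.0715) and Txn1 (-0.36, 0.0786) did not pass, nor did Prodh2 (0.0504) and Txn1 (0.0523) with median-ratio scaling. Apoa2 was at -0.70 with the length trend removed and passed (0.0445), but with no filter on low values it (0.0777), Mid1ip1 (0.0505) and Gadd45b (0.0502) did not. At the preset correlation the fatty acid and triglyceride list was called as higher without wildtype 12 (camera adjusted p = 0.0247) or knockout 9 (0.0177), and with an estimated correlation, over all 8 libraries, its adjusted p was 0.888. The immediate early list was called as lower without wildtype 12 (0.0414), and the urea cycle list without knockout 11 (0.0292), against 0.690 and 0.966 with an estimated correlation over all 8 libraries.

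In the growth hormone and IGF axis 2 of 17 genes rose, Egfr (0.82) and Igfbp4 (0.59), and 1 fell, Igfbp2 (-0.88), with 2 and 1 adjusted over the list alone. Of 6 tested cell cycle genes 2 rose, the cyclin genes Ccnd1 (1.67, limma adjusted p = 0.00231) and Ccne1 (0.50), and 0 fell (2 and 1 adjusted over the list alone). Of 23 unfolded protein response genes 2 rose, Asns (1.43) and Chac1 (0.77), and 2 fell, including Trib3 (2 and 2 adjusted over the list alone). The unfolded protein response list was called as higher at the preset correlation without wildtype 3 (camera adjusted p = 0.0330) or knockout 11 (0.00360), against 0.945 with an estimated correlation over all 8 libraries. In pericentral zonation 3 of 15 rose, with Slc13a3 (1.15) and Cyp1a2 (0.52) as examples, and 3 fell, among them Cyp2c37 (3 and 3 adjusted over the list alone). In periportal zonation 1 of 20 rose, Cdh1 (0.76), and 3 fell, with Hsd17b6 (-1.36) and Hsd17b13 (-0.51) as examples (1 and 3 adjusted over the list alone). Single left-out libraries ended the calls of Egfr (wildtype 1 or 12, limma adjusted p up to 0.0627), Igfbp4 (wildtype 1 or 3 or knockout 3, up to 0.0687) and Igfbp2 (wildtype 1, 10 or 12 or knockout 3, 10 or 11, up to 0.0942). They also ended those of Ccne1 (each library but knockout 10, up to 0.108), Chac1 (wildtype 1, 3 or 12 or knockout 3 or 11, up to 0.0603), Cyp1a2 (wildtype 3 or 12, up to 0.0607) and Hsd17b13 (wildtype 1 or 10 or knockout 3, up to 0.0745). With the length trend removed, Igfbp2 (-0.65, limma adjusted p = 0.117) and Hsd17b13 (-0.35, 0.0983) did not pass. Without both knockouts 3 and 11, Igfbp4, Igfbp2, Ccne1, Asns, Chac1 and Hsd17b13 did not (up to 0.132), and Slc13a3 was at 0.72. With median-ratio scaling Igfbp2 and Hsd17b13 did not pass (up to 0.0900), with quantile normalization Igfbp2, Ccne1 and Hsd17b13 (-0.32) did not (up to 0.121), and with the GC trend removed Hsd17b13 did not (0.0890). With no filter on low values Igfbp4, Igfbp2, Ccne1 and Chac1 did not (up to 0.0905), nor did Ccne1 with library weights (0.0572).

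In autophagy and lysosome 1 of 21 genes rose, Wipi1 (0.44), and 2 fell, Gabarapl1 (-0.83) and Bnip3 (-0.67), with 1 and 2 adjusted over the list alone. Of 21 secreted liver hormones 1 rose, Tsku, and 3 fell, with Angptl8 and Rbp4 (-0.52) among the falls (1 and 3 adjusted over the list alone). In glycolysis and glucose uptake 3 of 20 fell and 0 rose, Gckr (-0.69), Gys2 (-0.65) and Khk (-0.60), with 3 adjusted over the list alone. In gluconeogenesis and glycogen output 1 of 19 fell, in fatty acid oxidation and ketogenesis 3 of 36, Ech1 (-0.69), Acadvl (-0.49) and Acadm (-0.47), and in the circadian clock 1 of 19, Bhlhe40 (-0.79). Of each of these 3 lists 0 genes rose, and 0 passed when adjusted over the list alone. Single left-out libraries ended the calls of Wipi1 (wildtype 1, 3 or 10 or knockout 3 or 11, limma adjusted p up to 0.0956), Rbp4 (wildtype 1, 3 or 10, up to 0.0739), Gys2 (each but wildtype 3 and knockout 10, up to 0.112) and Khk (each but knockouts 10 and 11, up to 0.114). They also ended those of Ech1 (wildtype 1 or 10, up to 0.0685), Acadvl (each but knockouts 9 and 10, up to 0.127), Acadm (each but wildtype 3 and knockout 10, up to 0.125) and Bhlhe40 (wildtype 1, 3 or 10, up to 0.0648). With the length trend removed, Rbp4 (-0.26, limma adjusted p = 0.143), Gys2 (-0.56), Khk (-0.42), Ech1 (-0.45), Acadvl (-0.37), Acadm (-0.35) and Bhlhe40 (-0.72) did not pass. Without both knockouts 3 and 11, the same genes, Angptl8, Gabarapl1 and Wipi1 did not (up to 0.181). With quantile normalization Gys2 (-0.40), Khk (-0.39), Ech1 (-0.45), Acadm (-0.24), Acadvl (-0.26), Bhlhe40 and Gabarapl1 did not pass (up to 0.207), and Bnip3 was at -0.45 and passed (0.0454). Median-ratio scaling ended the calls of Gys2, Khk, Acadm, Acadvl, Bhlhe40 and Rbp4 (up to 0.110), and removal of the GC trend those of Gys2, Khk, Acadm, Acadvl and Bhlhe40 (up to 0.0742). With no filter on low values Gys2, Khk, Acadm, Acadvl, Bhlhe40, Wipi1 and Rbp4 did not pass (up to 0.0951), nor did Gys2 with library weights (0.0515).

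For 4 lists that camera did not call, limma passed 0 members: interferon response (22 tested, 1 at an unadjusted p under 0.05), Kupffer cell and macrophage markers (16 and 3), stellate cell and fibroblast markers (12 and 1) and red cell transcripts (6 and 1). Ordinary least squares also passed 0 members of each, and 0 passed when adjusted over the list alone. Lists with fewer than 3 tested members were described only. Of the cholangiocyte markers 2 were tested, of which 0 passed in limma or by ordinary least squares and 2 had an unadjusted p under 0.05 and passed when adjusted over the list alone, and of the pancreas and adipose transcripts 2 were tested, of which 1, Cela1, fell (-0.73, and -0.47 with the length trend removed) and 1 passed when adjusted over the list alone.

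Library composition was compared by exact two-sided permutation tests, which cannot give a p below 0.0286 for 4 against 4 libraries. The 50 highest genes took 53.3% ± 1.35 of total FPKM in wildtype and 58.9% ± 1.26 in knockout libraries (SD, n = 4, exact p = 0.0286). Totals and shares of FPKM here include exact zeros that can be failed estimates. Alb was at 0 in knockout 10, and Mup17 was above 0 only in knockouts 3 and 11, at 29001 and 25389 FPKM. The sum of Y-linked transcripts was 48.3 ± 1.74 and 38.6 ± 7.06 FPKM (SD, n = 4, exact p = 0.0286), and all 8 libraries held them, at 30.9 or more. Xist was at 0.0195 ± 0.0114 and 0.0989 ± 0.0265 FPKM (SD, n = 4, exact p = 0.0286). It was at most 0.118 in any library, near the floor and below the mean of 1 FPKM needed for testing. Of the 4 tested sex chromosome transcripts 1 fell in limma, Eif2s3y (-0.45, limma adjusted p = 0.0480), and 1 did so adjusted over the list alone. Eif2s3y did not pass without wildtype 1, 3, 10 or 12 or knockout 3 or 11, each alone (limma adjusted p up to 0.12), nor without both knockouts 3 and 11 (0.172), with no filter on low values (0.0870), with median-ratio scaling (0.0507) or with quantile normalization (0.118), and with median-ratio scaling the Y-linked sum had an exact p of 0.0571. Pancreas and adipose transcripts summed to 62.6 ± 6.65 and 38.2 ± 6.01 FPKM (SD, n = 4, exact p = 0.0286). Of the 18 members with values only 2 reached a mean of 1 FPKM, and 1 of these, Cela1, fell, so this sum rests on few genes. Each check with an exact p of 0.0286 had a Benjamini-Hochberg adjusted p of 0.0643 over the 9 checks. Group means of red cell transcripts (exact p = 0.429), the mitochondrial share (exact p = 0.457) and total FPKM (exact p = 0.771) did not differ beyond the spread between libraries. The mitochondrial share was 32.2% and 28.7% in knockouts 9 and 10, above each wildtype library (22.0% to 24.9%). In knockouts 3 and 11 it was 21.6% and 20.2%, below each of them, so the knockout mean hides a split.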

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

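The comparison of Foxo1 in wildtype 12 with the knockout libraries, and the target list repeated without G6pc and Igfbp1, were chosen after the result was seen. The library values of the named genes and of the composition checks were screened for a library far from the other 3 of its group, by Dixon's criterion. Of 219 groups 9 met it, where chance would give 10.95.

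In wildtype 12 G6pc was at 26.2 FPKM, far below the other wildtype libraries. The other values, given without an explanation, were C3 in wildtype 3 (1131 FPKM, the lowest), Cyp2c37 in knockout 3 (7.43, the lowest), Egfl7 in knockout 10 (16.2, the highest), Mid1ip1 in wildtype 1 (25.2, the lowest) and Acot3 in wildtype 1 (8.18, the highest). Foxo6 was at 0.0127 FPKM in wildtype 1 and at 0.0115 in knockout 10, with 0 in the others of each group. Red cell transcripts summed to 3560 FPKM in knockout 10, the highest of its group.

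G6pc and Igfbp1 in wildtype 12 lay near the knockout values. A mislabelled library is argued against by Foxo1, which in wildtype 12 was 10.2 times the highest knockout value. For collection at another time of day, the median absolute log2 deviation of the circadian clock genes was 0.25 in wildtype 12. It was 0.18, 0.48 and 0.42 in wildtypes 1, 3 and 10, and wildtype 12 lay -0.24 from the largest of these. This argues against a shift in wildtype 12 that exceeds the scatter of the other wildtype libraries and leaves a smaller one open. Lower activity of FoxO1 targets in wildtype 12 stays open: their median was -0.01, with 2.38% of 10000 expression-matched lists at or below it, but 14 of the 28 members were lower and 14 higher, and without G6pc and Igfbp1 the share was 25.3%. That members moving both ways leave this test undecided was settled after its value was seen.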

How the results depend on the processing

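Trend removal along length and GC content, leaving out knockouts 3 and 11 together, leaving out genes with a 0 and scaled library checks were chosen after seeing the data. Against 277 higher and 1195 lower genes, the counts were 485 and 720 with median-ratio scaling, 470 and 652 with quantile normalization, 516 and 585 with the length trend removed by symmetric loess, 458 and 698 by least squares, 549 and 812 with the GC trend removed, 199 and 656 without knockouts 3 and 11, 169 and 861 with ordinary least squares, 38 and 63 at an absolute log2 change of at least 1, and 516 and 1741 at an adjusted p under 0.1. Thresholds and fewer libraries change counts by construction; for the scalings and trends the cause was not tested. Leaving out 1 library at a time gave 102 (wildtype 1) to 360 (knockout 9) higher and 599 (wildtype 1) to 1294 (knockout 9) lower genes; higher genes also moved by over 1.5 times without wildtype 3 (160), wildtype 10 (145) and knockout 3 (161), and lower genes without wildtype 10 (744), wildtype 12 (745) and knockout 3 (725). Of the 1472 genes 809 were also called with the length trend removed by symmetric loess, 917 by least squares, and 696 without knockouts 3 and 11, and all of these kept their direction. Apoc3, Slc3a1, Dhcr7 and Mid1ip1 lost their calls with the symmetric loess and kept them with the least-squares one.

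The numbers 3 and 10 occur in both groups, and the correlations of the deviations of same-numbered libraries were -0.00791 and 0.0224, so the numbers are not taken to pair the libraries. With the number as a replicate block, 1 gene was higher and 1 lower, and Foxo1 had a log2 change of -1.69 (limma adjusted p = 0.175). This fit leaves few residual degrees of freedom. Its genotype effect rests on the libraries numbered 3 and 10, since the other numbers occur in a single group. Among the values of named genes given below that no longer passed, 84 came from this block. Foxo1 kept its direction and passed under the other 21 alternatives, between -3.24 and -1.68 (adjusted p over all alternatives 1.60e-05 to 0.175); the stricter filter on mean FPKM removes it.

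Camera with an estimated correlation called 0 lists in place of 8, and the other alternatives called 6 to 10, the leave-one-out ones among them 6 (knockout 3) to 10 (wildtype 12). Fry, which asks whether members move one way and does not compare them with other genes, called 7, including the FoxO1 targets (adjusted p = 0.0226). List medians changed sign in 77 of 797 values under alternatives, in 17 lists, 0 of these among the called lists and the FoxO1 targets. Over the alternatives, named genes other than Foxo1 gave 2259 values, of which 1865 were the same in direction and side of the threshold, 370 no longer passed, 23 newly passed and 1 changed sign, Pck1 under quantile normalization (0.049, adjusted p = 0.892, over all its alternatives 0.206 to 0.892). Of the 86 named genes that passed, 39 passed under each alternative that gave them a value, apart from the block: 32 of them had a value under all 23, while 7 had none with the stricter filter and 1 of these none with genes with a 0 left out. The exact test of the Y-linked sum gave p = 0.0571 with median-ratio scaling. FPKM carry no counts, so counting error per gene was not computed.

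Median log2 changes of lists, with the value for the main settings in parentheses after each name, were as follows, and the cause of these changes was not tested. FoxO1 targets in liver (-0.28) was called with fry (-0.28, adjusted p = 0.0226). Gluconeogenesis and glycogen output (-0.21) was called with knockouts 3 and 11 left out (-0.36, adjusted p = 0.0200) and changed sign with quantile normalization (0.044). Glycolysis and glucose uptake (-0.042) changed sign with median-ratio scaling (0.066), quantile normalization (0.13), library weights (0.033), the length trend removed (0.045), it removed by least squares (0.026) and the GC trend removed (0.034), and ranged from -0.15 (knockout 10) to 0.0077 (knockout 3) with 1 library left out. Fatty acid and triglyceride synthesis (0.043) was called with library weights (0.12, adjusted p = 0.0252) and with wildtype 12 (adjusted p = 0.0247) or knockout 9 (0.0177) left out, and ranged from -0.043 (wildtype 3) to 0.19 (wildtype 12) with 1 library left out. Cholesterol synthesis (0.37) was not called with an estimated correlation (0.37), fry (0.37) and knockouts 3 and 11 left out (0.17). Fatty acid oxidation and ketogenesis (-0.20) changed sign with quantile normalization (0.053). Lipoproteins and sterol transport (-0.050) was called with fry (-0.050, adjusted p = 0.0473) and changed sign with median-ratio scaling (0.059), quantile normalization (0.15), the length trend removed (0.10), it removed by least squares (0.059) and the GC trend removed (0.038), and ranged from -0.13 (knockout 11) to 0.013 (wildtype 10) with 1 library left out. Insulin signalling (-0.060) changed sign with median-ratio scaling (0.028), quantile normalization (0.00014), the GC trend removed (0.051) and knockouts 3 and 11 left out (0.073), and ranged from -0.15 (knockout 9) to 0.034 (wildtype 10) with 1 library left out. Growth hormone and IGF axis (-0.038) changed sign with a mean FPKM of at least 5 (0.0059), median-ratio scaling (0.068), quantile normalization (0.14), the block (0.050), the GC trend removed (0.10) and knockouts 3 and 11 left out (0.059), and ranged from -0.093 (knockout 10) to 0.065 (knockout 9) with 1 library left out. Male-biased liver genes (0.50) was not called with an estimated correlation (0.50) and fry (0.50). Female-biased liver genes (-0.44) was not called with a mean FPKM of at least 5 (-0.30) and an estimated correlation (-0.44), and ranged from -0.63 (knockout 9) to -0.33 (knockout 11) with 1 library left out. Sex chromosome transcripts (-0.12) changed sign with the GC trend removed (0.012) and knockouts 3 and 11 left out (0.029). Cytochrome P450 and drug metabolism (-0.55) was not called with an estimated correlation (-0.55). Urea cycle and amino acid breakdown (-0.15) was called with knockouts 3 and 11 left out (-0.34, adjusted p = 0.000326) and with knockout 11 left out (adjusted p = 0.0292) and changed sign with quantile normalization (0.032), and ranged from -0.28 (knockout 11) to -0.046 (knockout 9) with 1 library left out. Acute phase (0.88) was not called with an estimated correlation (0.88), fry (0.88) and knockouts 3 and 11 left out (0.14). Interferon response (-0.0012) changed sign with a mean FPKM of at least 5 (0.0062), median-ratio scaling (0.084), quantile normalization (0.088), library weights (0.066), the block (0.14, adjusted p = 0.00683), the length trend removed (0.10), it removed by least squares (0.075), the GC trend removed (0.072) and knockouts 3 and 11 left out (0.093), and ranged from -0.10 (knockout 10) to 0.046 (wildtype 12) with 1 library left out. Kupffer cell and macrophage markers (-0.070) changed sign with median-ratio scaling (0.024), quantile normalization (0.0080), the length trend removed (0.17), it removed by least squares (0.13), the GC trend removed (0.037) and knockouts 3 and 11 left out (0.073). Lymphocyte and neutrophil markers (2.13) was not called with no filter (0.0049), median-ratio scaling (2.22), quantile normalization (2.18), an estimated correlation (2.13), fry (2.13), the length trend removed (2.56), it removed by least squares (2.46), the GC trend removed (2.24) and knockouts 3 and 11 left out (0.52), and ranged from 1.21 (knockout 11) to 2.94 (knockout 9) with 1 library left out. Stellate cell and fibroblast markers (-0.089) changed sign with the length trend removed (0.019), it removed by least squares (0.00058), the GC trend removed (0.0099) and knockouts 3 and 11 left out (0.23), and ranged from -0.21 (knockout 9) to 0.043 (knockout 3) with 1 library left out. Sinusoidal endothelial markers (-0.24) was not called with a mean FPKM of at least 5 (-0.49), library weights (-0.24), the block (-0.23), an estimated correlation (-0.24), fry (-0.24) and knockouts 3 and 11 left out (-0.11), and ranged from -0.36 (knockout 10) to -0.18 (knockout 3) with 1 library left out. Cell cycle (0.10) was called with no filter (0.13, adjusted p = 3.68e-06) and fry (0.10, adjusted p = 0.0361). Unfolded protein response (0.15) was called with a mean FPKM of at least 5 (0.16, adjusted p = 0.0497) and knockouts 3 and 11 left out (0.44, adjusted p = 0.000331) and with wildtype 3 (adjusted p = 0.0330) or knockout 11 (0.00360) left out, changed sign with the block (-0.033), and ranged from -0.10 (knockout 9) to 0.35 (knockout 11) with 1 library left out. Circadian clock (-0.047) changed sign with median-ratio scaling (0.023), quantile normalization (0.0023), the length trend removed (0.0035) and the GC trend removed (0.045), and ranged from -0.16 (knockout 9) to 0.018 (wildtype 12) with 1 library left out. Autophagy and lysosome (-0.086) changed sign with quantile normalization (0.049). Respiratory chain (-0.52) was not called with an estimated correlation (-0.52). Immediate early genes (-0.51) was called with no filter (-0.35, adjusted p = 0.0281), fry (-0.51, adjusted p = 0.0264), the GC trend removed (-0.44, adjusted p = 0.0459) and wildtype 12 left out (adjusted p = 0.0414), and ranged from -0.61 (wildtype 10) to -0.49 (knockout 10) with 1 library left out. Secreted liver hormones (0.0041) changed sign with no filter (-0.0046), library weights (-0.032) and the block (-0.11), and ranged from -0.12 (knockout 11) to 0.044 (wildtype 1) with 1 library left out. Periportal zonation (-0.14) was called with knockouts 3 and 11 left out (-0.33, adjusted p = 0.0298) and changed sign with quantile normalization (0.065).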

Other observations

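The splits of the libraries for gene counts, the test on mitochondrial transcripts, 2 of the 3 tests on reads shared between paralogs, the comparison of drug metabolism medians per library, and leaving out knockouts 3 and 11 were chosen after the result was seen, and the estimator of the single-fragment value was replaced after its first version was seen. Without knockouts 3 and 11, 10 of 42 genes of urea cycle and amino acid breakdown fell and 0 rose (camera adjusted p = 0.000326), as did 4 of 19 genes of gluconeogenesis and glycogen output (0.0200), both at the preset correlation. With an estimated correlation, over all 8 libraries, the adjusted p of both lists was 0.966. The gluconeogenesis median was -0.44 and -0.23 in knockouts 9 and 10 and -0.26 and 0.094 in knockouts 3 and 11, so knockout 3 was as low as knockout 10. The median of the amino acid list was -0.36 and -0.23 in knockouts 9 and 10, and -0.11 and 0.11 in knockouts 3 and 11. With all 8 libraries its falls included Cth (-0.71), Tdo2 (-0.41), Haao (-0.39) and Hgd (-0.52), genes of cysteine, tryptophan and tyrosine metabolism. Unfolded protein response genes had a median of 0.56 and 0.20 in knockouts 9 and 10 and of -0.14 and -0.43 in knockouts 3 and 11. Over all alternatives the adjusted p lay between 0.000326 and 0.966 for the amino acid list, between 0.0200 and 0.966 for gluconeogenesis and glycogen output and between 0.000331 and 0.945 for the unfolded protein response, and the highest of each came with an estimated correlation.

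Albumin was at 0 FPKM in knockout 10, and Mup17 was above 0 only in knockouts 3 and 11 of the 8 libraries, at 29001 and 25389 FPKM. Gm27747 was at 0 in knockouts 3 and 10 and between 687 and 1224 FPKM in the other 6 libraries. The first principal component of log2 values held 44.1% of the variance and placed knockouts 3 and 11 at 38.7 and 27.7, knockouts 9 and 10 at 4.94 and 5.07, and the wildtype libraries between -20.9 and -17.3. Within 10 Mb of Foxo1 7 of 34 tested genes were called (20.6%), against 14.4% elsewhere (Fisher's exact two-sided p = 0.323), which decides neither for nor against donor strain sequence carried along with the allele.

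Among the 35 splits of the 8 libraries into 4 and 4, the genotype split gave 1472 genes and the highest other split 8. Thus 1 split gave as many, the fewest that 35 splits can give. The other splits mix the genotypes, which widens the spread within their groups, so the test by itself does not exclude chance. For gene lists chance cannot be excluded. The genotype split called 8 lists with the preset correlation, 24 of the 35 splits called as many, and the highest other split called 20.

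Shorter genes were lower in the knockout libraries. The authors' effective-length normalization is argued against by the value of a single fragment in short relative to long genes, which differed by -0.0197 (SE 0.0267) on the log2 scale between knockout and wildtype, while a first version, from the lowest values, gave -0.126 (SE 0.295) and decided nothing. The pattern was not confined to genes with ribosomal, respiratory chain, spliceosome or proteasome names. The 844 short genes without such names had a median -0.19 from that of all genes. They are most of the 1015 shortest genes in which the pattern was seen. This median therefore cannot tell a trend in the library or its processing from a change of expression, and both stay open. Over the 13 mitochondrial protein genes rho with length was 0.341, which left open whether these follow length. The respiratory chain median, -0.52, had 0.64% of 10000 lists matched on length and expression at or below it, so an added decrease remains a hypothesis, in genes that vary together.

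Drug metabolism genes were lower in the knockout libraries. Knockouts 3 and 11, with their high acute phase transcripts, did not carry the fall alone. The mean of knockouts 9 and 10 gave a drug metabolism median of -0.40 against wildtype. Taken per library this median was -0.39 and -0.33 in knockouts 9 and 10 and between -0.14 and 0.14 in the wildtype libraries. Without knockouts 3 and 11, 3 acute phase genes were still higher and 2 lower, so a milder acute phase state in knockouts 9 and 10 stays open as a cause. Reads shared between paralogs stay open. Of the 17, 5 lie outside the Cyp2c, Cyp3a, Gsta and Ces1 subfamilies, Cyp2a5, Cyp2e1, Gstt1, Fmo1 and Nr1i3, which met the bound set beforehand, but Cyp2a5 has a similar copy, Cyp2a4, and the bound did not take into account how many other genes fell. With Cyp2a counted among the subfamilies, 4 of 22 tested members outside them fell and 2 rose. That share, 18.2%, was not shown to differ from the 11.5% of tested genes outside the list that fell (Fisher's exact two-sided p = 0.312). Of the 4, only Nr1i3, 1 gene, was called with each single library left out. Cyp2e1 was not called without wildtype 1, 10 or 12 or knockout 3 or 11 (limma adjusted p up to 0.0988). Gstt1 was not called without wildtype 1 (0.0526), nor Fmo1 without any single library but knockout 11 (up to 0.118). Leaving out libraries shows how far a call rests on 1 of them and cannot decide on shared reads. A gene length trend could contribute, since 12 of the 17 passed after its removal, between the bounds set beforehand. The list as a whole was still called then at the preset correlation (camera adjusted p = 0.000162). A decrease with the genotype stays a hypothesis.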
